A study of Homo sapiens with 4 samples.

How the data were processed

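The series measured RNA by sequencing in 4 libraries of Jurkat cells that expressed dCas9-KRAB and an inducible guide RNA against a regulatory element of ALDH1A2. Groups were taken from the sample titles and the labelled control or knockout state, 2 libraries of sgRNA minus and 2 of sgRNA plus. Per the labels' protocols, total RNA was extracted with a miRNeasy kit after 72 hours with doxycycline, and strand-specific libraries were sequenced as single-end reads of 100 bases on a BGISEQ instrument. The treatment text, doxycycline included, is the same for all 4 libraries, and the labels do not say whether sgRNA minus cells lacked the guide or its induction.

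The submitters' processing notes name STAR 2.5.2a, featureCounts, DESeq2 1.12.4 and the genome build hg19. The gene annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. Per the file headers, the authors deposited 1 table of the comparison with no column for a single library. Its mean normalized count per feature is a signal that the authors averaged over all libraries after scaling. The authors' fold change is on a log2 scale, with an SE on the same log2 scale, per the file headers. The authors' Wald statistic is a score equal to the fold change divided by its SE, as checked on the values. The authors' p-value is the two-sided normal probability of that statistic, and the deposited adjusted p-value is the Benjamini-Hochberg value over 12824 features, as recomputed. Of 21146 features, 4522 have a mean of 0 and no p-value, and 3800 have a p-value but no adjusted one because their mean lies below that of all tested features. Of the 12824 tested features, 1021 carry an XLOC identifier and no gene symbol. Tested features hold 99.949% of the summed mean counts, so the threshold on low values left out few reads.

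The plan made before the data were examined was a count model on values per library. Because the values deposited are the authors' own comparison, the alternative fixed in the same plan was used: the authors' adjusted p under 0.05 gave the calls, and no count model was refitted. No batch, replicate or GC term could therefore be added to the authors' model. The authors' normalization was described from 746 features whose mean equals 1 read in a single library, which take 4 distinct values and give the 4 scaling factors.

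A total of 34 gene lists had been fixed in advance, and 31 with at least 3 tested members were tested. The test was cameraPR of limma 3.58.1 in R 4.3.3 on the authors' Wald statistics, with the inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists. Each list's median log2 fold change was also ranked among 10000 random lists matched on mean expression in 20 bins. A correlation estimated per list needs values per library and was not used here. Presets of 0.05 and 0.1 were tried in its place. The test takes genes as its units, so its p-values do not measure the spread between libraries or cultures. Members were also adjusted over the list alone. Genes named in the text are ALDH1A2, the 10 largest rises and falls among called genes with a mean count of at least 50, without features that carry only a clone or locus number, the tested locus neighbours, up to 4 members of each list past its threshold in its direction and up to 2 called members of each other list. Others are named as members of a group or as chosen after their values were seen.

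GC content and length were those of the longest transcript per gene in GENCODE release 29, which matched 90.9% of tested features by identifier. This annotation and the gene order of GRCh38.p14 are of another build than the authors' hg19, so no coordinates are printed. A lowess curve with a span of 0.3 was fitted to the fold changes on GC content and then on log2 length, and its fitted values were subtracted. The authors' SEs were kept, so this correction changes the fold changes and not their errors. The statistics then had an SD of 0.62, so calls of single genes made in this way are strict. SDs of the statistics over genes were worked out from their interquartile range. It was chosen after the data were seen. Fractions of the calls, medians and trends were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

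The procedures were tested on simulated data built on the 12824 tested genes and the authors' SEs. Simulated genes were independent of each other and had exactly the authors' SEs, and scores in the list runs were independent too. Error rates near their nominal level follow from that set-up, so they check the procedures and not how correlated real genes behave. With 200 genes changed in each of 20 runs, 5.01% of calls were unchanged genes. The gene list test called a list shifted by 1 SD in 90% of 100 runs and 0.167% of lists with no shift, and 5% of 200 unshifted lists fell outside the central 95% of matched lists. On 11655 genes with a simulated GC trend of the observed slope, the correction called 84.7% of genes changed 2-fold, with 5.55% of calls unchanged genes. The simulated noise had the full authors' SEs, whereas the real statistics after the correction had an SD of only 0.62. These 2 rates therefore do not describe the correction on the real data. The correction with an empirical null on top was not simulated. The alternatives tried were other filters on low values, other thresholds, recentred fold changes, an empirical null, features with a symbol only, and the corrections and presets named here.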

Results

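RNA was sequenced from Jurkat cells, an established human T cell acute lymphoblastic leukaemia line, that carried dCas9-KRAB, a catalytically dead Cas9 fused to a transcriptional repressor domain, and an inducible single-guide RNA (sgRNA). The guide directed the repressor to a regulatory element of ALDH1A2, which encodes a retinaldehyde dehydrogenase that makes retinoic acid. The series asked how expression differed once ALDH1A2 had been depleted in this way. It held 4 libraries in 2 groups, 2 labelled sgRNA minus (control) and 2 labelled sgRNA plus, with RNA taken 72 hours after induction. The labels give the same treatment text, with the inducer doxycycline, for all 4 libraries and do not say what set sgRNA minus apart; they give no density or oxygen of the cultures. The labels number the libraries within a group but do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The values come from the authors' deposited table of the single comparison, which lists a mean normalized count over all libraries, a log2 fold change with its standard error (SE), a Wald statistic and p-values for 21146 features.

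Mean normalized counts in the authors' deposited table summed to 19976330. The libraries' scaling factors, worked out from 746 features in the authors' deposited table with a single read, ran from 0.995 to 1.01, a range of 1.015-fold in the authors' normalization; read totals per library were not analysed here. The authors' deposited table gives an adjusted p-value for 12824 features, called tested genes here. Among tested genes of the authors' deposited table, the median SE of the log2 fold change was 0.15, with 0.12 at mean counts of at least 1000 and 0.50 at mean counts under 100. With these SEs, simulated changes of 1.5-fold were called in 52.5% of cases, 2-fold in 77.5% and 3-fold in 88.8%, but 1.2-fold in 5.6%, so small differences were not detectable at this depth and number of libraries.

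ALDH1A2 (ENSG00000128918, on chromosome 15), the gene the guide was aimed at, had a log2 fold change of -4.35 ± 0.16 (SE) in the authors' deposited table, at a mean normalized count of 1478. Its level in sgRNA plus was 4.91% of that in sgRNA minus, with a 95% interval of 3.97% to 6.07% from the SE in the authors' deposited table. The adjusted p of its Wald test in the authors' deposited table was 8.57e-167, the smallest among all tested genes. The table's header does not state which group is the numerator. The fold change was read as sgRNA plus over minus because ALDH1A2 is negative, and every direction given here rests on that reading. Values per library were not analysed here, so the depletion could not be read in each library.

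At an adjusted p under 0.05, the authors' deposited table calls 49 of the 12824 tested genes, 45 lower and 4 higher in sgRNA plus. The lower genes were led by adrenomedullin, glycolytic enzymes and hypoxia-inducible genes, and the higher ones were enzymes and a transporter of amino acid metabolism. Of the 45 lower genes, 18 belonged to the glycolysis or hypoxia lists, which hold 39 tested genes between them, 26 belonged to neither and the last was ALDH1A2. Each list has 24 symbols and is not complete, so the 26 were not shown to lie outside these responses. The smallest call of the authors' deposited table was PGK1, 21.4% lower. Unadjusted p-values under 0.05 numbered 627 in the authors' deposited table, 447 lower and 180 higher, against 641 expected by chance, or 321 in each direction. Tested against a 1.2-fold change with the SEs of the authors' deposited table, 13 genes were called, all lower, and none of the 4 rises passed.

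**Figure D1:**
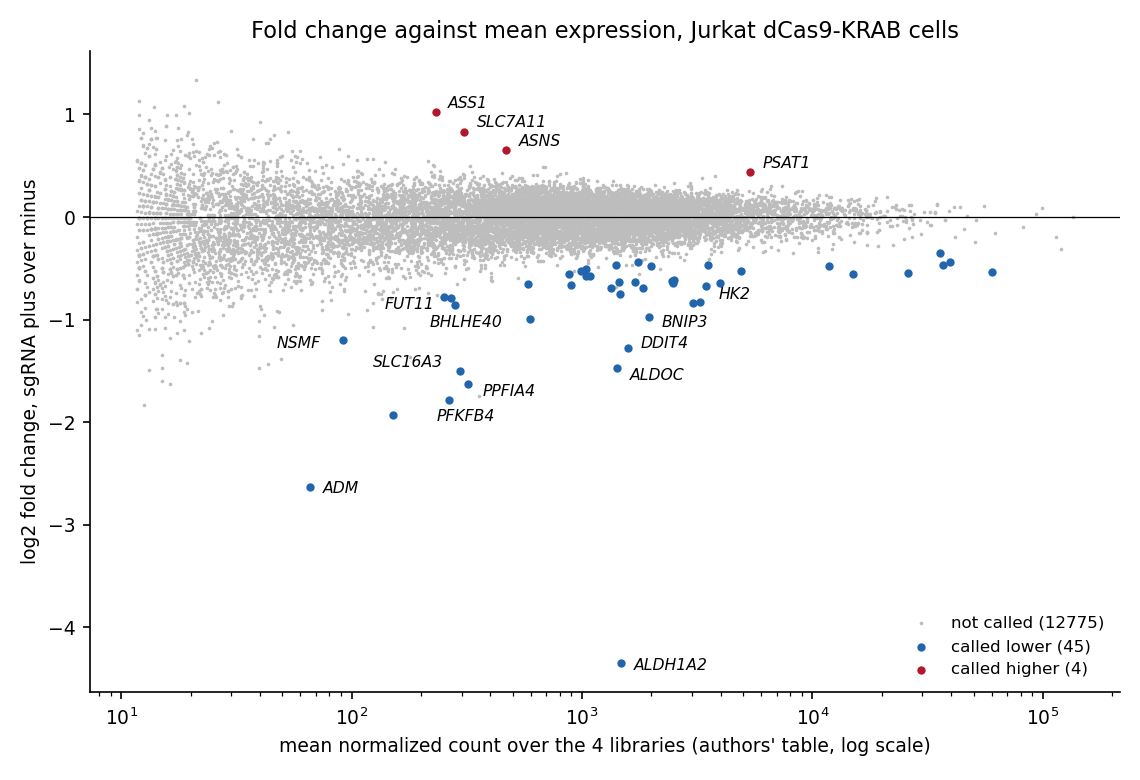
Log2 fold change (sgRNA plus over minus, y axis) against the mean normalized count over the 4 libraries (x axis, log scale) for the 12824 tested genes of the authors' deposited table. Blue points are the 45 genes called lower and red points the 4 called higher; ALDH1A2 lies lowest, at -4.35.

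The 10 largest falls after ALDH1A2, among called genes with a gene symbol and a mean count of at least 50, ranged from -2.63 to -0.86 on the log2 scale in the authors' deposited table. ADM, which encodes the vasoactive peptide adrenomedullin, fell the most in the authors' deposited table (log2 fold change -2.63 ± 0.40, adjusted p 9.74e-08), at a mean count of only 66.1. PFKFB4, an isoenzyme that sets the level of the main allosteric activator of phosphofructokinase, was 71.0% lower in the authors' deposited table (-1.78 ± 0.21, adjusted p 3.85e-14). PPFIA4, of the liprin family of scaffold proteins, had -1.62 ± 0.23 in the authors' deposited table (adjusted p 9.15e-10). SLC16A3, an exporter of lactate, had -1.50 ± 0.19 and ALDOC, an aldolase, -1.47 ± 0.14 in the authors' deposited table, with adjusted p-values of 2.98e-11 and 5.80e-22. DDIT4, an inhibitor of mTOR signalling, fell to 41.3% of sgRNA minus in the authors' deposited table (-1.28 ± 0.12, adjusted p 6.33e-22). NSMF, BHLHE40, a transcriptional repressor, BNIP3, a mitophagy receptor, and FUT11, a fucosyltransferase, had -1.20, -0.99, -0.97 and -0.86 in the authors' deposited table, with SEs of 0.31, 0.18, 0.16 and 0.20. The call on NSMF, whose transcript has a GC content of 65.0%, ended once the trend with GC content described further on was removed (-0.95, adjusted p 0.476). The authors' SEs were kept there. With the statistics also rescaled by their narrower spread over genes NSMF was called (adjusted p 1.97e-04 of the rescaled Wald statistic). A p-value rescaled in this way is set against the spread over genes and does not measure the spread between libraries. A called feature that the rule passes over, because it carries a locus number and no gene symbol, fell more than PFKFB4 in the authors' deposited table (XLOC_009280, -1.93, adjusted p 1.39e-08); it is named after its value was seen.

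Glycolytic genes were lower from glucose uptake to lactate export. Of the 24 tested genes of the glycolysis list, 14 were called lower and none higher in the authors' deposited table, and 21 were called lower when adjusted over the list alone. The called falls in the authors' deposited table ran from 21.4% for PGK1 to 71.0% for PFKFB4. They took in glucose uptake (SLC2A1), hexokinase (HK1, HK2), aldolase (ALDOA, ALDOC), enolase (ENO1), pyruvate kinase (PKM), lactate dehydrogenase (LDHA) and lactate export (SLC16A3). PFKL, PGAM1 and GAPDH were not called, with -0.42, -0.35 and -0.31 in the authors' deposited table (adjusted p 0.0535, 0.0702 and 0.193). HK2, the inducible hexokinase, had -0.67 ± 0.11 in the authors' deposited table (adjusted p 2.42e-07). The list's median log2 fold change was -0.47 in the authors' deposited table, below all 10000 random lists matched on mean expression. On the authors' Wald statistics, limma's cameraPR test gave an adjusted p of 1.93e-66. With the inter-gene correlation preset at 0.1 in place of 0.01, the cameraPR adjusted p was 4.03e-25. Genes are the units of this test, so neither value measures the spread between libraries. PFKM, LDHB and SLC16A1, the 3 members above 0, had 0.01, 0.05 and 0.09 in the authors' deposited table and were not called. With the GC and length trends removed the list's median was -0.44 (cameraPR adjusted p 2.06e-103). The smaller p goes with a narrower spread of the statistics over all genes and not with a larger fall. From the interquartile range that spread was an SD of 0.62 against 1.16. Of the 14 called genes HK1 lost its call with the authors' SEs kept (-0.41, Wald adjusted p 0.158). With the statistics rescaled by that narrower spread HK1 was called (adjusted p 1.06e-05 of the rescaled Wald statistic). The rescaled value is set against the spread over genes and not between libraries. Several of these genes, such as GAPDH, ENO1, LDHA and PGK1, have processed pseudogenes, and how shared reads were counted is not given in the sources used here.

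Hypoxia-inducible genes were lower as well. Of 20 tested, 7 were called lower and none higher in the authors' deposited table, 16 lower when adjusted over the list alone, with a median of -0.58 (cameraPR adjusted p 4.35e-43). The 5 tested genes that are also in the glycolysis list did not carry this result. Without them, 15 genes kept a median of -0.55 in the authors' deposited table and 4 calls, ADM, BNIP3, DDIT4 and NDRG1, with a cameraPR adjusted p of 8.86e-26. The 19 glycolysis genes outside the hypoxia list had a median of -0.44 in the authors' deposited table, 11 calls and a cameraPR adjusted p of 4.34e-49. With the GC and length trends removed the hypoxia list had a median of -0.61 (adjusted p 4.76e-90).

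**Figure D2:**
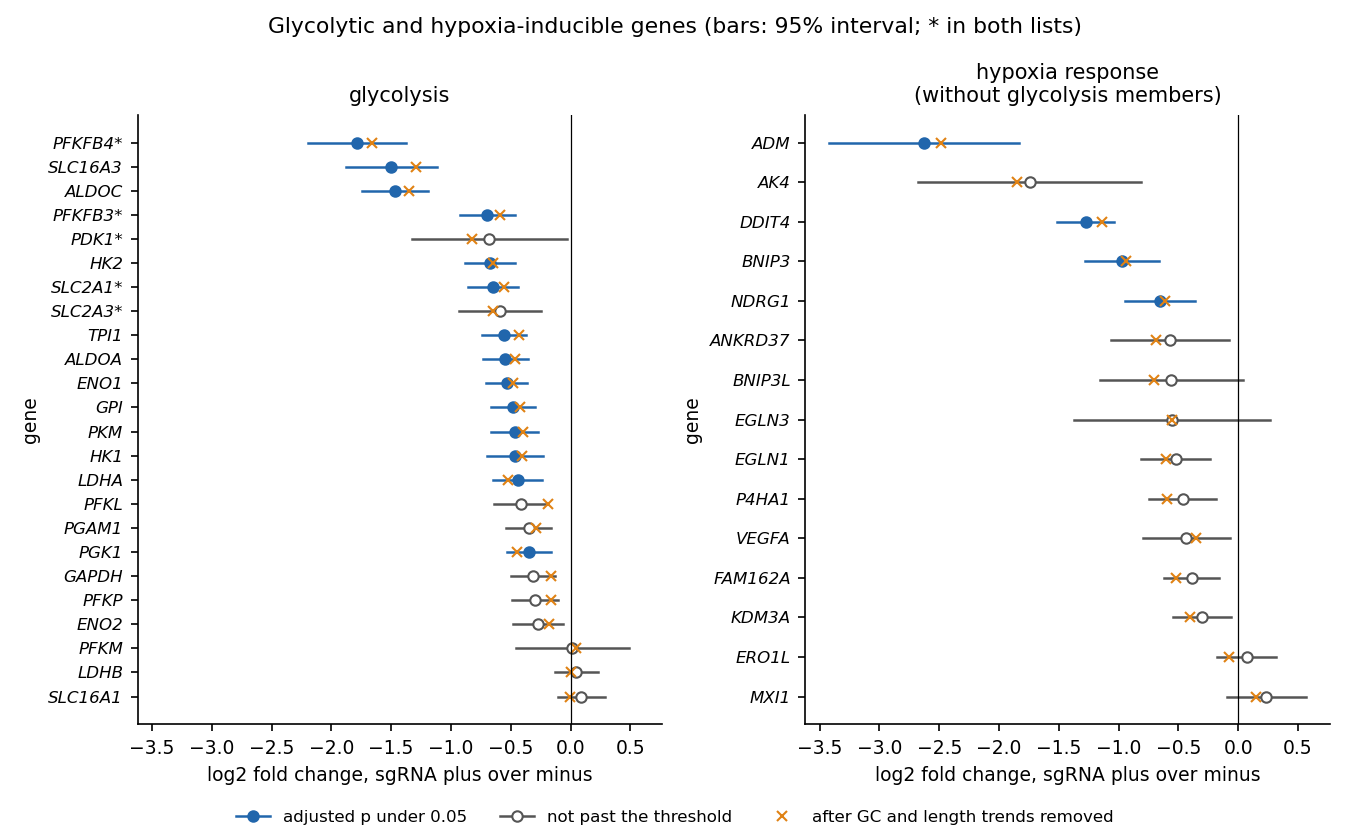
Log2 fold change (sgRNA plus over minus, x axis) of each tested gene of the glycolysis list (left) and of the hypoxia list without shared members (right), with 95% intervals from the SE of the authors' deposited table; blue filled points have an adjusted p under 0.05. Orange crosses mark the values with the GC and length trends removed. In the glycolysis list 21 of the 24 points lie below 0.

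The 4 genes called higher belong to amino acid metabolism. ASS1, argininosuccinate synthase of the arginine pathway, was 2.03-fold higher in the authors' deposited table (log2 fold change 1.02 ± 0.21, adjusted p 8.24e-04). SLC7A11, the cystine importer, had 0.83 ± 0.19 in the authors' deposited table (adjusted p 0.00457). ASNS, asparagine synthetase, and PSAT1, of serine synthesis, had 0.65 ± 0.16 and 0.44 ± 0.11 in the authors' deposited table (adjusted p 0.0244 and 0.0215). SLC7A11, ASNS and PSAT1 are in the list of ATF4 targets and amino acid response genes, where 3 of 26 tested genes were called higher and 1, DDIT4, lower in the authors' deposited table. Adjusted over the list alone, 3 were higher and 2 lower. The list's median in the authors' deposited table was 0.05 and it was not past its threshold (cameraPR adjusted p 0.35). The SLC7A11 and PSAT1 transcripts are poor in GC, at 35.4% and 42.3%. With the GC and length trends removed and the authors' SEs kept, ASS1 stayed called (1.15, adjusted p 6.00e-05). SLC7A11 (0.66, adjusted p 0.128), ASNS (0.62, adjusted p 0.0503) and PSAT1 (0.33, adjusted p 0.524) did not, whereas the list's median rose to 0.13 and passed (adjusted p 5.87e-04). Whether the list would pass at a higher inter-gene correlation with the trends removed was not tested. With the statistics also rescaled by their narrower spread over genes, SLC7A11, ASNS and PSAT1 were called. Their adjusted p-values of the rescaled Wald statistic were 5.67e-06, 4.84e-07 and 2.63e-04. These values do not measure the spread between libraries.

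Fold changes followed the GC content of the transcripts. Across 11655 tested genes with a known transcript, the rank correlation of GC content with the log2 fold change of the authors' deposited table was -0.71; genes are not independent replicates, so no p-value is given. In the decile of genes with the lowest GC content, 31.3% to 38.5%, the median log2 fold change of the authors' deposited table was 0.16, and in the highest decile, 61.6% to 74.2%, it was -0.23. The correlation held in each of 5 bins of mean expression, from -0.45 in the lowest bin to -0.82 in the highest. Transcript length had a rank correlation of 0.21. Among genes with a mean count of at least 1000, removal of both trends took away 51.3% of the variance of the fold changes. Of the 44 genes called lower that have a GC content, 41 lie above the median of tested genes, 48.5%. With the trends removed, 38 genes were called, 32 of them among the 49 of the authors' deposited table. Labels name no library batch, so a batch and the group cannot be told apart.

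**Figure D3:**
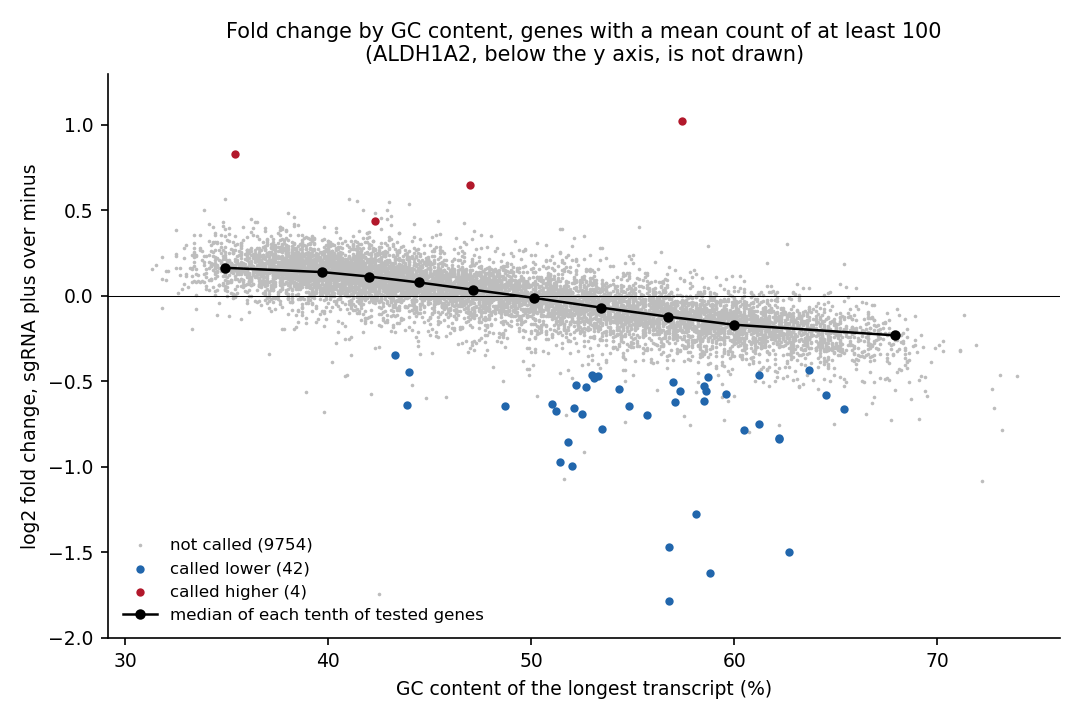
Log2 fold change of the authors' deposited table (y axis) against the GC content of each gene's longest transcript in percent (x axis), for genes with a mean count of at least 100; blue points were called lower and red points higher. Black points give the median of each decile of all tested genes, which goes from 0.16 at the lowest GC content to -0.23 at the highest.

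Immediate early genes respond within minutes to signalling. The list of immediate early and activation genes was lower as a list although none of the 17 tested was called in the authors' deposited table. The median was -0.25 (cameraPR adjusted p 0.00212), 3 members had an unadjusted Wald p under 0.05 in the authors' deposited table, and 1 was lower when adjusted over the list alone. EGR1 had -1.47 ± 0.49 in the authors' deposited table at a mean count of 39.5 (adjusted p 0.376). JUN, JUNB and JUND had -0.42 ± 0.28, -0.42 ± 0.19 and -0.39 ± 0.17 in the authors' deposited table, each with an adjusted p of 0.891. The list is rich in GC, with a median of 55.9%, and with the GC and length trends removed its median was -0.14, still at a percentile of 0.145 among matched random lists, and its call ended (adjusted p 0.0513); with an inter-gene correlation of 0.1 in place of 0.01 it ended too (adjusted p 0.135).

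The cholesterol synthesis list passed its test with members on both sides of 0. The median of 23 tested genes was -0.13 in the authors' deposited table (cameraPR adjusted p 0.00225), with 15 below 0 and 8 above, 1 called lower, none called higher and 3 lower when adjusted over the list alone. MVD, mevalonate diphosphate decarboxylase, had -0.44 ± 0.12 in the authors' deposited table (adjusted p 0.0468). LSS, DHCR7 and FDPS had -0.34, -0.36 and -0.13 in the authors' deposited table and adjusted p-values of 0.233, 0.376 and 0.891. MVD, at 63.7% GC, lost its call with the trends removed (-0.21, adjusted p 1). The list kept its own, with a median of -0.09 (adjusted p 5.87e-04), but not with an inter-gene correlation of 0.1 (adjusted p 0.195).

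Lists close to the function of ALDH1A2 did not pass. The medians in the authors' deposited table were -0.07 for 14 genes of retinoid metabolism and receptors, -0.22 for 13 genes induced by retinoic acid, both with a cameraPR adjusted p of 0.35, and 0.05 for 8 members of the aldehyde dehydrogenase family other than ALDH1A2 (adjusted p 0.755). Unadjusted Wald p-values under 0.05 in the authors' deposited table numbered 1, 0 and 2 in these lists, and no member was called. Of the 13 genes induced by retinoic acid, 10 lay below 0 in the authors' deposited table, and their median was at a percentile of 2.185 among matched random lists, just outside the central 95%. The list has a median GC content of 56.8%, and with the trends removed its median was -0.07, at a percentile of 20.6. Lists of the leukaemia's own regulators gave -0.02 for 18 genes of the TAL1 complex and its targets, -0.11 for 16 NOTCH targets and -0.02 for 29 genes of T cell identity in the authors' deposited table, with cameraPR adjusted p-values of 0.676, 0.235 and 0.35 and 2 unadjusted p-values under 0.05 in each. With the trends removed the T cell list's median was -0.04, at a percentile of 1.86 among matched random lists, against 16.45 before, and it did not pass (cameraPR adjusted p 0.218).

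Genes beside ALDH1A2 were compared because dCas9-KRAB can silence chromatin around its target. The neighbour list, fixed in advance, holds 17 symbols, and 10 genes of it were tested. These were TCF12, ZNF280D, POLR2M, LIPC, ADAM10, FAM63B, SLTM, RNF111, CCNB2 and MYO1E. AQP9 and CGNL1 were among those not tested. Their log2 fold changes in the authors' deposited table ran from -0.06 for CCNB2 to 0.30 for LIPC, with a median of 0.08. None was called and 0 had an unadjusted Wald p under 0.05 in the authors' deposited table; the lowest adjusted p was 0.891. For the 8 with a mean count above 100, the lowest 95% bound in the authors' deposited table was -0.26. LIPC and MYO1E had low counts, and over all 10 the lowest bound in the authors' deposited table was -0.98, so larger falls of those 2 genes were not excluded. The neighbours are poor in GC, with a median of 41.4%. With the trends removed the list's median was -0.04 and the lowest bound of the 8 was -0.41. POLR2M overlaps other transcription units, so its reads may not be its own. Features that carry only an XLOC identifier have no position here, so whether any lies beside ALDH1A2 was not seen.

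The other lists did not pass with the authors' threshold on low values. Cell cycle lists had medians near 0 in the authors' deposited table, -0.01 for 37 genes of DNA replication and 0.06 for 38 genes of mitosis, with cameraPR adjusted p-values of 0.393 and 0.2. With the trends removed the replication median was -0.04, at a percentile of 0.43 among matched random lists, and the list did not pass (cameraPR adjusted p 0.568). Respiratory chain genes (percentile 2.025) and ribosome biogenesis genes (99.13) also left the central 95% with the trends removed and did not pass (cameraPR adjusted p 0.0672 and 0.222). In energy metabolism the medians were -0.02 for 25 genes of the TCA cycle, -0.003 for 37 nuclear genes of the respiratory chain, 0.07 for 30 mitochondrial ribosome proteins and -0.05 for 28 fatty acid genes in the authors' deposited table (cameraPR adjusted p 0.755, 0.35, 0.35 and 0.354). Antioxidant NRF2 targets, of which SLC7A11 was called higher, had 0.01, unfolded protein response genes 0.04 and heat shock genes 0.06 in the authors' deposited table (cameraPR adjusted p 0.795, 0.35 and 0.393). The p53 targets had -0.03, apoptosis regulators -0.03, ribosome biogenesis genes 0.0003 and 50 cytosolic ribosomal proteins -0.03 in the authors' deposited table (cameraPR adjusted p 0.676, 0.806, 0.755 and 0.2). The median of the ribosomal proteins was at a percentile of 1.61 among matched random lists. Medians of -0.16 for NF-kappaB targets, -0.12 for HLA genes and 0.05 for interferon genes in the authors' deposited table had cameraPR adjusted p-values of 0.324, 0.35 and 0.676. Replication-dependent histones, of which 7 were tested, had a median of -0.64 in the authors' deposited table with all 7 below 0, and did not pass (cameraPR adjusted p 0.2), although the median was at a percentile of 0.16 among matched random lists. Their main transcripts lack a poly(A) tail and their counts were low; without the threshold on low values, 22 histone genes entered and the list passed (cameraPR adjusted p 0.00345). Markers of other cells were scarce: 6 B cell and 3 epithelial or fibroblast markers had medians of -0.21 and -0.14 in the authors' deposited table (cameraPR adjusted p 0.35 for both), and 2 myeloid and 2 erythroid markers were too few for a test. For the aldehyde dehydrogenase family and the p53 targets the test's direction was opposite in sign to the median. Mitochondrially encoded transcripts were not analysed here.

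**Figure D4:**
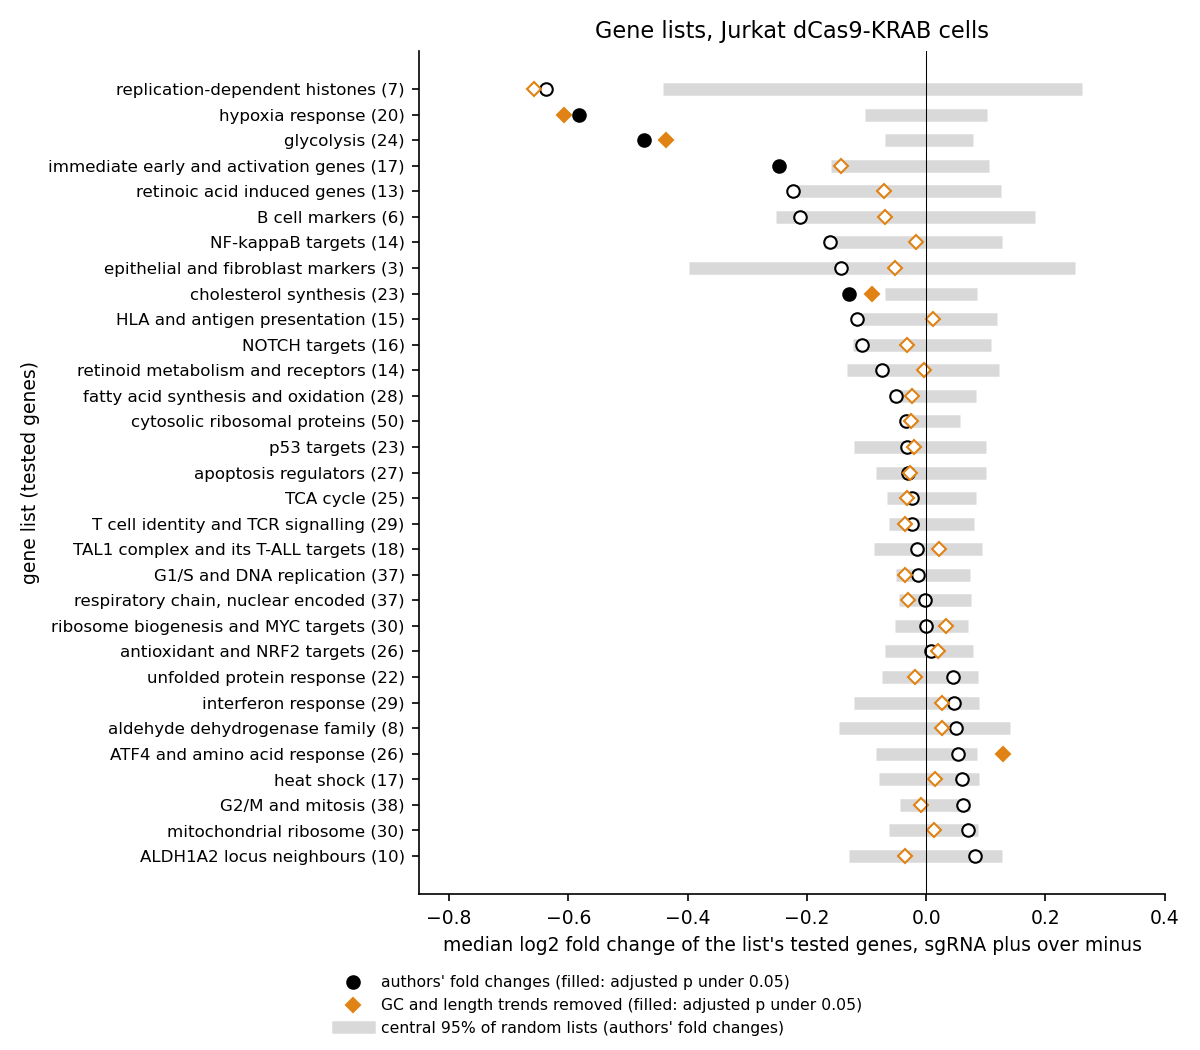
Median log2 fold change (sgRNA plus over minus, x axis) of each of the 31 gene lists with a test, with the number of tested genes in brackets; black circles use the fold changes of the authors' deposited table and orange diamonds those with the GC and length trends removed, filled where the adjusted p was under 0.05. Grey bars span the central 95% of 10000 random lists matched on mean expression for the authors' fold changes. Glycolysis, hypoxia, cholesterol synthesis and replication-dependent histones lie below their bars under both.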

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

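The filters and thresholds were chosen before the data were examined; the recentred fold changes, the empirical null, the 1.2-fold test, the symbol restriction, the GC and length corrections, the correlation presets, the ranks and the lists without ALDH1A2 or shared members were chosen after. No paired analysis was possible because the deposited table has no column for a single library. For the same reason leaving out each library, other size factors, other count models, fry and an estimated inter-gene correlation were not run.

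ALDH1A2 stayed past the threshold and negative under each of the 9 alternatives run for it, from -4.35 to -4.32. The count of 49 called genes came to 46 without a filter on low values and on equal totals, 49 with a mean of at least 10 in both groups, 48 with symbols only and 38 with GC and length trends removed. It moved further under a stricter adjusted p of 0.01 (32 genes, 2 higher), a fold of at least 1.5 (31, with 28 lower), an empirical null that rescales the statistics by their own spread (32, 2 higher) and a test against a 1.2-fold change (13, of which 13 lower and 0 higher). The stricter p, the fold minimum and the 1.2-fold test ask for more by construction; the empirical null did so here because the statistics were spread wider than an SD of 1. With GC and length trends removed, 1 gene in place of 4 was higher. With an empirical null on top, which divides by the narrower spread of 0.62 over genes, the calls were 130, 113 lower and 17 higher. Of the 49, 47 were among them. Calls rescaled in this way do not measure the spread between libraries.

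Of the 4 lists past the threshold, 2 were left with an inter-gene correlation of 0.1, glycolysis and hypoxia, which passed under each of the 10 alternatives. Cholesterol synthesis (cameraPR adjusted p 0.195) and the immediate early and activation list (0.135) did not pass at 0.1. Immediate early genes also lost their call with trends removed (0.0513), where the ATF4 list gained one (5.87e-04). Higher inter-gene correlations were not run with trends removed, so the ATF4 call was not tested in that way. Without a filter on low values 5 lists passed, because replication-dependent histones, with 22 genes in place of 7, gained a call (0.00345). The naming rule gives 33 genes other than ALDH1A2. Of these the 10 locus neighbours, EGR1, JUN, JUNB, JUND, LSS, DHCR7 and FDPS had no call to lose. Among the calls on the rest, the test against 1.2-fold ended 8, the trend removal 5 and the empirical null 4. Equal totals, no filter or the trend removal with an empirical null ended 1 each, MVD, while EGR1 passed under the last of these. No direction of a called gene turned. Low counts limit what can be seen: at mean counts under 100 the median SE was 0.50.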

Other observations

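The tests of the GC relation, of scatter at low counts, of the hypoxia genes outside glycolysis of the ATF4 list and of the 20 nearest genes were chosen only after the results were seen. With GC and length trends removed, 6 genes were called that the authors' deposited table does not call, each lower in sgRNA plus. Hypoxia-inducible genes made up 4 of them: AK4, an adenylate kinase (-1.85), EGLN1, an oxygen-sensing prolyl hydroxylase (-0.60), P4HA1, a collagen prolyl hydroxylase (-0.59), and FAM162A (-0.52), with adjusted p-values of 0.0297, 0.0165, 0.0139 and 0.00415. The others were UQCRFS1, the Rieske protein of the respiratory chain (-0.40, adjusted p 0.0202), and THEMIS, a T cell signalling protein (-0.51, adjusted p 0.0202). All 6 have less GC than the median gene, so the trend lay against their fall. The SE of AK4 was 0.47 at a mean count of 358. PDK1 and BNIP3L, picked from the hypoxia list for their SEs, had 0.33 and 0.30 at mean counts of 1399 and 1773. DDIT4 of the same list had 0.12 at 1582, which is the median SE at counts of at least 1000. AK4, PDK1 and BNIP3L thus had wide errors for their counts, and their values per library were not analysed.

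The list of ATF4 targets and amino acid genes passed its test with the trends removed. Higher presets of the inter-gene correlation were not run there, so whether the list would still pass at them was not tested. SLC7A11, ASNS and PSAT1 lost their own calls there with the authors' SEs kept. ASNS did so narrowly, with 0.65 before and 0.62 after (Wald adjusted p 0.0503). In the list of ATF4 targets 21 of 26 genes lay above 0 once the trends were removed, with a median of 0.13 that exceeded all 10000 matched random lists. With an empirical null on top, 4 of the list were called higher, SLC7A11, ASNS, PSAT1 and PCK2, and 2 lower, DDIT4 and STC2. The other 13 of the 17 genes higher under that setting, named after their values were seen, were ASS1, YARS, GARS, GPT2, RPL35, RPS25, NACA, MRPL21, MRPL36, HSPE1, HSPB11, LONRF1 and GXYLT2. DDIT4 and STC2 also respond to hypoxia. A stress response of mitochondria, such as doxycycline gives by blocking their ribosomes, is a candidate explanation that would raise this list. Its median stood at a percentile of 86.1 among matched lists before the trends were removed, inside their central range, so the test did not decide, and the labels give all 4 libraries the same doxycycline text without saying how the sgRNA minus cells differed.

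The decline of fold changes with GC content is the widest pattern in the table. A link of GC content with abundance is argued against, since within 5 bins of mean expression the highest rank correlation was -0.45. A difference between the groups in library preparation or sequencing may produce such a slope, and the correlation of -0.71 over all genes would follow from it. No library batch is labelled and no values per library were analysed, so preparation cannot be told apart from an effect of the guide. An SD of the statistics, from their interquartile range, of 1.16 before removal and 0.62 after shows how much of that spread the trends held.

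Of 3 technical explanations for the fall of glycolytic genes, centring by the authors' normalization stays open: the list's median lay 0.475 below that of all tested genes, but the normalization itself sets the latter near 0, so a fall of the list cannot be told apart from a rise of the rest. High abundance, and GC content and length as the whole cause, are argued against by a percentile of 0 among lists matched on abundance and by a median of -0.436 after the trends were removed. Slower proliferation, a biological alternative, would have lowered both the replication and mitosis lists, and neither was called lower. Their medians were -0.0135 (17 genes above 0, 20 below) and 0.0622 (26 above, 12 below). Both lay above the bound of -0.1 set beforehand, which was the outcome written down against this explanation. It is still left open, because the replication list lay low among matched lists once the trends were removed. With trends removed the replication median of -0.0356 was at a percentile of 0.43 among matched lists, though that list did not pass (cameraPR adjusted p 0.568). The mitosis median was then -0.00864, at a percentile of 24.72. A response shared with hypoxia-inducible genes is a hypothesis written after both lists were seen to be lower. The cameraPR adjusted p of 8.86e-26 for the hypoxia list without its glycolysis members restates that pattern and is no separate support. Whether such a response follows from ALDH1A2, or from oxygen or cell density in culture, was not tested. Nor was doxycycline, which the labels give for all 4 libraries.

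Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, lay low in sgRNA plus: 21 of 22 with reads were below 0, with a median of -0.805 at a median mean count of only 7.39. Scatter of low counts that is independent from gene to gene is argued against, as is GC content or length bias. The median was at a percentile of 0 among matched random lists both before and after the trends were removed, where it was -0.732. Matched lists hold unrelated genes, so a difference between libraries that the histone genes share is not covered by this comparison. Fewer cells in S phase stays open too. The replication list's median of -0.0135 lay above the bound of -0.1 set beforehand and the list was not called lower. With trends removed, however, that median was -0.0356 at a percentile of 0.43. Less carry-over of transcripts without a poly(A) tail may account for it and stays open, since 0 other such transcripts with reads were found in the table; an effect of the guide was not tested. None of the 7 histone genes with an adjusted p was called, and 0 had an unadjusted Wald p under 0.05.

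Spread of the repression to neighbouring genes was a hypothesis written down before its test. The median of the 10 tested neighbours was 0.0823, and of the 20 nearest tested genes by the order of GRCh38.p14, 10 on each side, 0 were called and 0 had an unadjusted Wald p under 0.05. Their median of 0.0946 became -0.028 with GC and length trends removed, so no spread over these genes as a set was seen at this depth. For single genes with low counts large falls are not excluded: the lowest 95% bound was -0.98 in the neighbour list and -1.85 among the 20. The first tested gene on one side, LIPC, had a mean count of 20.7 and a 95% interval of -0.90 to 1.51. On the other side POLR2M had -0.25 to 0.42. The set median rests mostly on genes farther away, so repression confined to the closest genes was not decided. Features that carry only an XLOC identifier have no position here and could not enter either set. XLOC_009280, which was called lower, is among them.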
